A study of Mus musculus with 14 samples.

How the data were processed

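H3K4me3 ChIP-seq was done on cerebral cortex of C57BL/6J mice aged 3 months, per the labels. Tissue samples of 50 mg were fixed in 1% formaldehyde, libraries were made with 18 PCR cycles and fragments of 170 to 300 bp, and 36 cycles were read on an Illumina Genome Analyzer, per the labels' protocols. Groups were taken from the labels: postnatal-only nicotine and saccharin, 4 libraries each, and pre- and postnatal nicotine and saccharin, 3 libraries each. The treatment text is the same for every sample and describes delivery to pregnant mice from conception, removal at day 21 and rest to day 90. It does not describe a postnatal-only course, so that exposure is known here from the group names alone. The labels do not say that replicates are separate animals, so the p-values measure the spread between samples.

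The authors gave 1 table per exposure with values for each library in a common set of regions on build mm9, and edgeR is named per the submitters' processing notes. The deposited values are a signal: read counts per region already adjusted with edgeR, not whole and never negative, each table adjusted on its own. The aligner, the peak caller, the versions and the filters are not given in the sources used here. Each table held 19203 rows, of which 14881 had values and 4322 repeated region coordinates with empty values and were left out. Regions were 611 to 4705 bp wide (median 1583) and both tables listed identical regions. 11388 regions carried a gene in the tables and 3493 did not. 11224 transcript identifiers of the tables were found in a gene name table (assembly GRCm38.p6), which was used for names only and gave back 15 symbols that a spreadsheet had turned into dates. Positions within exons or introns were not analysed here.

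The raw depth of a library is unknown, since adjusted counts do not give it back. Summed signal was 2004918 to 2489860 per postnatal library and 1445810 to 2372855 per pre- and postnatal library. The medians per library were 79.8 to 84.2 and 52.8 to 56.9.

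A count model had been planned only for whole counts. As the values were not whole, the fallback fixed before the data were examined was applied: limma 3.58.1 with trend in R 4.3.3, on log2 of the value with a pseudocount of 1, over regions with at least 1 in at least as many samples as the smaller group, with Benjamini-Hochberg adjusted p under 0.05. Tests were two-sided and each exposure was fitted on its own. The fit of all 8 postnatal libraries, also fixed in advance, was changed after the values were seen. Libraries 1 and 2, and 3 and 4, of each postnatal group differed with a variance 1.00 to 1.07 times that of counting noise (r 0.979 to 0.981), against 2.29 to 2.60 times for other pairs within a group (r 0.959 to 0.965). Counting noise was judged over regions with a mean of 10 to 1000 by reading the adjusted values as counts, which at unknown depth is a rough guide. Their means were therefore used as single samples, and the fit of 8 libraries was kept as an alternative.

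24 gene lists were fixed before the data were examined, and those with at least 5 measured genes were tested with camera (inter-gene correlation 0.01) and with Benjamini-Hochberg adjustment over the lists. The region with the highest mean stood for a gene. Estimated correlation and fry were run beside it, and members were also adjusted over the list alone. The genes named were fixed by rule: per exposure and direction the 10 named regions past the threshold or, where fewer passed, those with the lowest unadjusted p, without predicted genes, then Ash2l, Mef2c, Chrna4, Chrnb2 and Chrna7, and the 2 members of each list with the lowest p. Some of these list members are not reported here. The strongest regions and those called under alternatives were named after their values were seen. Exposures were compared by the correlation of fold changes across regions and by a z test of the difference of both fits. The share of signal in regions with a postnatal mean over 3000 was compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

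The fits were tested on simulated data with 200 changed regions in each of 5 draws. With the postnatal design, 28.1% of regions changed 1.5-fold, 55.8% changed 2-fold and 89.4% changed 4-fold were called, with 36 false calls. With the pre- and postnatal design the shares were 9.25%, 40.6% and 79.1%, with 27 false calls. The mitochondrial respiratory chain list was the only list shifted, by 0.3 on the log2 scale. It was called by camera in 5 of 5 draws in both designs, and with an estimated correlation in 0 of 5 and 2 of 5. Camera also called 1 other list in the pre- and postnatal design and 0 in the postnatal one. The simulated spread was taken from the fits, which already hold counting noise, and counting noise was then drawn again. It was independent between samples, which may share a batch, and between regions. In the pre- and postnatal data the estimated correlation was 0.045 for the mitochondrial list and 0.217 for the homeobox list. The shares are therefore a rough guide and not limits. The list calls say little for lists whose genes move together. Alternatives covered quantile normalization, abundance-trended offsets, filters, pseudocounts of 0.1 and 5, the replicate number as a block, regions summed per gene, each library left out, and the share of signal in the strongest regions as a term in the model.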

Results

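H3K4me3, a histone mark found mainly at active promoters, was profiled by ChIP-seq in the cerebral cortex of 3-month-old C57BL/6J mice exposed to nicotine or saccharin solution during development. Saccharin served as the control. 14 libraries were compared in 4 groups: 4 nicotine and 4 saccharin libraries after postnatal-only exposure, and 3 nicotine and 3 saccharin libraries after exposure before and after birth. Each exposure had its own saccharin controls and its own table of values for the same set of regions (build mm9). The summed signal per library, in read counts already adjusted by the submitters, ran from 2004918 to 2489860 in the postnatal table and from 1445810 to 2372855 in the pre- and postnatal table. Raw sequencing depth is unknown, so no counting intervals are given. In the postnatal table, libraries 1 and 2 of a group, and libraries 3 and 4, differed with a variance 1.00 to 1.07 times that of counting noise, if the adjusted values are read as counts, against 2.29 to 2.60 times for other pairs within a group. Each such pair was averaged and counted as 1 sample, which left n = 2 against 2, with n = 3 against 3 for the pre- and postnatal exposure.

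Some regions of high signal are given first, picked after their values were seen. In postnatal saccharin samples the region at Cpeb2, which encodes a regulator of mRNA translation, held a signal of 1082 ± 83.0 (SD, n = 2). The regions at Cdk13, a kinase acting on RNA polymerase II, and at Arid1b, a subunit of the BAF chromatin remodelling complex, held 916 ± 67.7 and 830.1 ± 48.0. The region at Yy1, a zinc finger transcription factor, held 805 ± 47.1, and that at Mdga2, an adhesion protein of synapses, 729 ± 460.2. The median over tested regions in these samples was 83.4. Signal is summed over a region and grows with its width (r = 0.792 between the logarithms), and all of these regions but that at Mdga2 are wider than the median of 1583 bp. Far above all of these stood 15 regions with a postnatal mean over 3000, most of them near positions 98.5 Mb on chromosome 2, 3.0 Mb and 35.1 Mb on chromosome 9 and 3.1 Mb on chromosome 12. Satellite-type repeats are known near these positions, although no repeat annotation was used. These 15 regions took 8.30% to 25.5% of the summed signal in the postnatal libraries and 19.1% to 49.7% in the pre- and postnatal ones. Their share did not separate the treatments: it was 17.6% ± 10.7 (SD, n = 2) with nicotine and 13.6% ± 7.22 with saccharin after postnatal exposure (exact two-sided permutation p = 0.667, the smallest possible being 0.333). After pre- and postnatal exposure it was 36.9% ± 15.9 (SD, n = 3) and 33.9% ± 5.61 (exact two-sided permutation p = 0.8, the smallest possible being 0.1). The Mdga2 region named above followed this share: its signal was higher in the postnatal samples of high share (high over low 1.52 on the log2 scale).

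**Figure D1:**
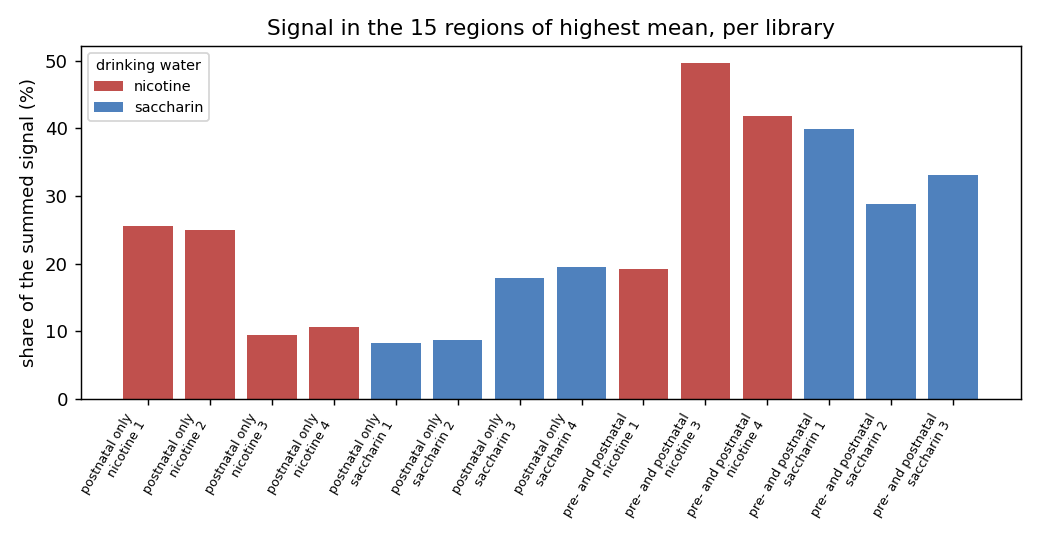
Share of the summed signal (%) held by the 15 regions of highest mean, 1 bar per library, red for nicotine and blue for saccharin. Postnatal nicotine libraries 1 and 2 (25.5% and 24.9%) stand apart from nicotine libraries 3 and 4 (9.41% and 10.7%).

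The first comparison asked whether nicotine confined to the postnatal period altered H3K4me3 in the adult cortex. The lowest p-values on the higher side belonged to Rhou, a small GTPase (chromosome 8, 126177229 to 126178729), with a signal of 359 ± 17.8 in nicotine samples against 276 ± 18.2 in saccharin samples (SD, n = 2 each), a log2 difference of 0.38 ± 0.11 (SE). Grin2d, which encodes an NMDA receptor subunit, had 132 ± 17.3 against 90.8 ± 4.87 (chromosome 7, 53087776 to 53089916), a log2 difference of 0.52 ± 0.15. Tdg, a DNA glycosylase that takes part in removing methylated cytosine, had 159 ± 3.36 against 120.5 ± 3.13, a log2 difference of 0.40 ± 0.13. On the lower side, Cadm2, a cell adhesion molecule of neurons, had 177 ± 5.43 against 227 ± 7.70 (log2 difference -0.36 ± 0.11). Pfkm, the muscle-type phosphofructokinase of glycolysis, had 42.7 ± 2.02 against 67.1 ± 8.34 (log2 difference -0.63 ± 0.23).

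None of these regions passed the test. In limma, 0 of 14873 regions had an adjusted p under 0.05 and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 281 regions (143 higher and 138 lower in nicotine), where chance alone gives 744. That count was 658 (404 higher and 254 lower) without saccharin libraries 1 and 2. The other named regions on the higher side were Zc3h7a (log2 difference 0.51), Klhl35 (0.48), Iars2, a mitochondrial tRNA synthetase (0.42), Stk17b, a kinase linked to apoptosis (0.42), Tox3, an HMG-box factor (0.37), Dcaf10 (0.37) and Rbfox2, a splicing regulator (0.33). On the lower side they were Tmem109 (-0.76), Ppapdc1b (-0.64), Fam113a (-0.52), Tpd52l2 (-0.51), Fam13c (-0.50), Prkg1, a cGMP-dependent kinase (-0.44), Mblac2 (-0.36) and Usp37, a deubiquitinase (-0.34). Nicotine and saccharin samples did not overlap at 29.1% of regions, and chance gives 33.3%. A difference between classes of samples that crosses treatment, described next, stayed in the residual spread of this fit. The low counts therefore do not show the absence of an effect. The median region had a 95% interval of ± 0.39 on the log2 scale, or 1.31-fold, before any adjustment for the number of regions.

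The share of signal in the 15 strongest regions parted the 4 postnatal samples into a high and a low class, each with 1 nicotine and 1 saccharin sample. Rhou differed by 0.39 on the log2 scale in the high class and by 0.36 in the low class, Grin2d by 0.34 and 0.71, and Cadm2 by -0.36 and -0.35. All 20 regions named for their low p-values had 1 direction in both classes. This follows from that choice, since in each the nicotine samples lay on 1 side of the saccharin samples, and it is no added support. Over 14858 regions the share with 1 direction was 53.3%. Zc3h7a itself differed between the classes (high over low 0.37 on the log2 scale, adjusted p = 0.0341). Leaving out a nicotine pair left 1 nicotine sample, and regions such as Mamdc2 and Smo then followed the class of that sample. Mamdc2 differed by -1.29 without nicotine libraries 1 and 2 and by 1.42 without nicotine libraries 3 and 4. Smo differed by -1.06 and 0.77 in the same fits. Both regions also differed between the classes (high over low 1.90 and 1.18). The count of 0 calls became 9 (8 higher and 1 lower) with the class as a term in the model, where 1064 regions (469 higher and 595 lower) had an unadjusted p under 0.05. Within both classes the nicotine sample had the higher share (25.2% against 18.7% in the high class, 10.04% against 8.47% in the low class). The class term, alone or with a scaling, therefore does not part the remaining difference in share from treatment. Among the 8 higher calls, Ank1, Mdga2, Cdk5rap2 and Litaf also differed between the classes (high over low 1.61, 1.52, 1.47 and 1.41). With the class the count of calls was 18 under quantile normalization and 21 with abundance-trended offsets, which held 6 and 9 of the 9 above. Of the 18, 3 were among the 15 strongest regions and 11 carried no gene, and of the 21 these were 3 and 13. Both sets also held weaker regions beside the strongest ones near 3.0 Mb on chromosome 9, such as 3008103 to 3008752 and 3010211 to 3010872. The counts of 3 therefore understate the calls from that stretch. With the offsets Grin2d was among the 21 (log2 difference 0.54 ± 0.13, SE, adjusted p = 0.0323 in limma). In the fits with class, limma took the variance from a trend shared by all regions (14873 degrees of freedom). This SE and adjusted p therefore do not measure the spread of Grin2d itself. The count of 0 became 1 with the replicate number as a block, at an unnamed region on chromosome 18 (56098825 to 56099778) chosen after its values were seen. That region also differed between the classes (high over low 1.47).

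5 genes had been fixed before the data were examined: Ash2l, a core subunit of H3K4 methyltransferase complexes, Mef2c, a transcription factor of neuronal differentiation, and the nicotinic acetylcholine receptor subunits Chrna4, Chrnb2 and Chrna7. After postnatal exposure the signal at Ash2l was 197 ± 8.48 with nicotine and 176 ± 18.6 with saccharin (SD, n = 2 each), a log2 difference of 0.17 ± 0.12 (SE). At Mef2c it was 52.0 ± 21.7 and 72.5 ± 18.9 (log2 difference -0.51 ± 0.27), and the difference was -0.35 within the high class and -0.67 within the low class. Its nicotine samples held 67.3 and 36.7 and its saccharin samples 59.2 and 85.9, so the groups overlapped. Mef2c also differed between these classes (high over low 0.69, adjusted p = 0.0105). The receptor subunits differed by 0.07 ± 0.16 for Chrna4, 0.24 ± 0.21 for Chrnb2 and 0.0066 ± 0.15 for Chrna7, which took opposite signs in the classes (0.27 and -0.26). None of the 5 passed the test.

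**Figure D2:**
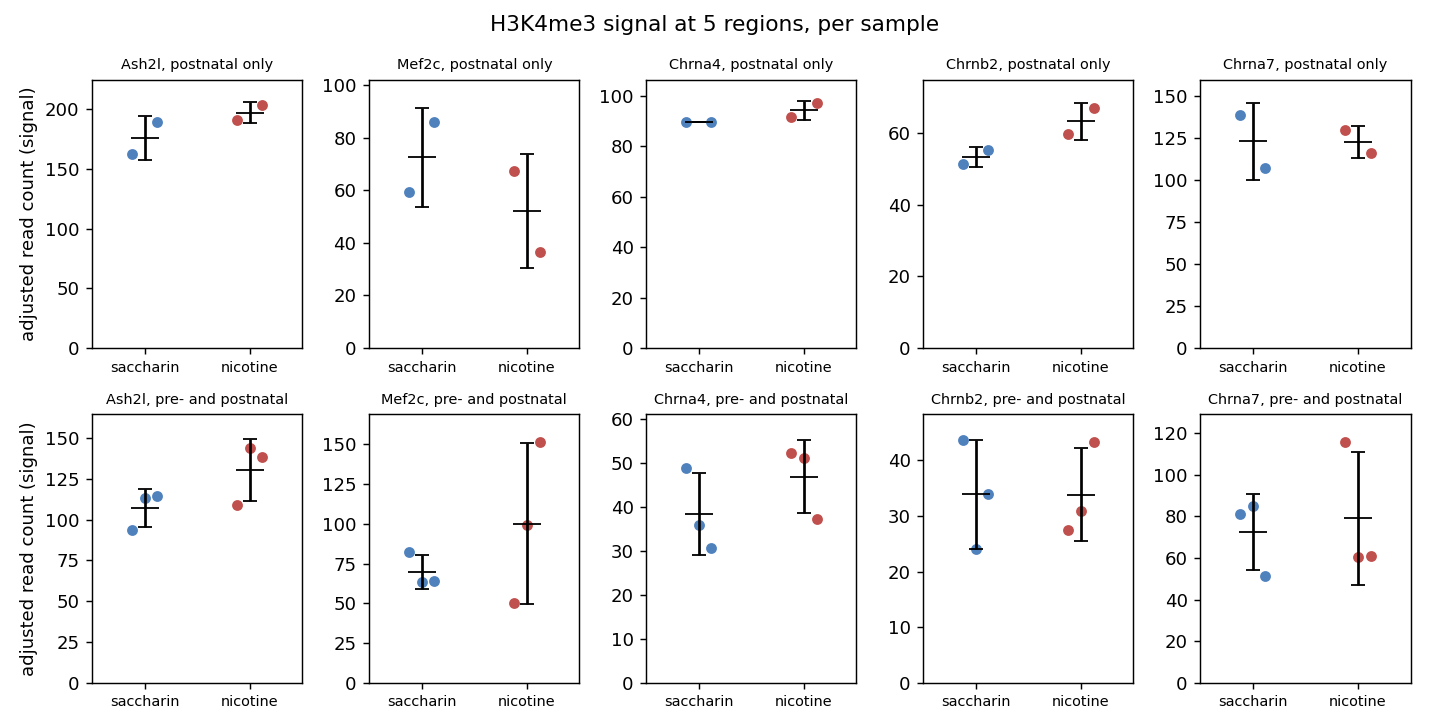
Adjusted read count (signal) at the regions of Ash2l, Mef2c, Chrna4, Chrnb2 and Chrna7, with 1 point per sample, the mean as a line and the SD as bars. Upper row postnatal exposure (n = 2 each), lower row pre- and postnatal exposure (n = 3 each): at Mef2c the nicotine mean lies under the saccharin mean in the upper row (52.0 against 72.5) and above it in the lower row (100.1 against 69.8), and neither difference passed the test.

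Of 24 gene lists fixed before the data were examined, 21 had at least 5 measured genes. After postnatal exposure 0 of the 21 passed in limma's camera test (smallest adjusted p = 0.663), with an estimated correlation 0 and in fry 0, and no member passed over all regions or when adjusted over the list alone. At an unadjusted p under 0.05 camera had 1 list, the H3K4 methyltransferase complex subunits (adjusted p = 0.663). 9 of its 15 genes lay higher in nicotine (median 0.05 on the log2 scale), among them Wdr5, a scaffold of these complexes (0.20 ± 0.11, SE). All 5 measured H3K4 demethylases lay higher (median 0.08), with Kdm2b at 0.15 and Kdm5b at 0.10. Kdm5b took the opposite sign with abundance-trended offsets (-0.0050).

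Neuronal groups moved little after postnatal exposure. Among 22 immediate early genes 14 lay lower (median -0.08), with Nptx2, a synaptic pentraxin, at -0.34 ± 0.15 (SE) and Bdnf, a neurotrophin, at -0.28 ± 0.20. Among 20 glutamate receptor genes 12 lay lower (median -0.07), with Grm3 at -0.33, while the strongest Grin2d region lay at 0.35. Of 6 nicotinic receptor subunits 4 lay higher (median 0.04), with Chrna3 at -0.42 ± 0.38. The median was 0.04 for 22 postsynaptic density genes (Homer2 0.27, Dlg2 -0.55), 0.04 for 20 GABA receptor and interneuron genes (Gabbr1 0.19, Gabra2 -0.21), and -0.06 for 17 projection neuron and layer markers (Tle4 0.22, Fezf2 -0.43). It was 0.03 for 37 dendrite and spine regulators (Ppp1r9a 0.33, Pak2 0.19), -0.01 for 29 presynaptic release genes (Stx1a -0.36, Syn2 0.16) and -0.03 for 17 monoamine and opioid genes (Oprd1 0.23, Drd4 -0.42). These 3 medians changed sign under quantile normalization and with abundance-trended offsets. For 9 MEF2 and class IIa histone deacetylase genes (Mef2b -0.32) the median was 0.05, the mean -0.07 and the direction of the test downward, and the median also changed sign under both scalings.

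Markers of other cell types and broad groups did not pass either. The median was -0.01 for 7 astrocyte markers (Gli3 0.11, Fgfr3 -0.14), where the sign changed under both scalings and fry pointed up while camera pointed down. It was -0.06 for 13 oligodendrocyte markers (Nkx6-2 0.26, Ugt8a 0.21), and 0.09 for 7 endothelial and mural markers (Vwf 0.80 ± 0.59, Sox17 0.23). For 13 genes of the list of neighbouring-region markers, named for choroid plexus and striatum, the median was 0.03 and the mean -0.05. The test pointed down (Gbx2, not a striatal member of the list, -0.73). 15 of 21 developmental homeobox regulators lay higher (median 0.10; Gata6, a zinc finger factor placed in this list, 0.45, and En2 0.21). The median was 0.03 for 20 imprinted genes (Cdkn1c, an inhibitor of cell division, 0.58 ± 0.20, and Commd1 -0.35) and -0.05 for 59 ribosomal protein genes (Rpl34 0.24, Rpl19 0.23). 29 of 44 mitochondrial respiratory chain genes lay lower (median -0.03; Sdhc -0.39, Sdha -0.29), and the median was -0.02 for 18 heat shock and stress genes (Hspa8 -0.24, Dnajb1 -0.21). 3 lists were too small to test: 4 microglia and macrophage genes (Irf8 0.57 ± 0.67), 1 clustered protocadherin (Pcdha2 -0.10) and 0 erythrocyte and blood genes. The signs of Irf8, Sox17 and Pcdha2 changed when a library pair was left out, and that of Fgfr3 when regions were summed per gene.

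The second comparison asked the same of nicotine given before and after birth. Zer1, a substrate receptor of a ubiquitin ligase, had a signal of 90.3 ± 4.30 in nicotine samples against 50.4 ± 3.27 in saccharin samples (SD, n = 3 each), a log2 difference of 0.83 ± 0.20 (SE; chromosome 2, 29978798 to 29980534). Gabarap, an autophagy protein that also binds GABA receptors, had 57.7 ± 13.2 against 30.9 ± 4.31, a log2 difference of 0.86 ± 0.28. Bad, a promoter of apoptosis, had 91.0 ± 36.1 against 47.6 ± 8.29 (0.85 ± 0.27). Lower signal lay at Ptpn14, a tyrosine phosphatase, with 26.4 ± 8.48 against 55.7 ± 3.39 (log2 difference -1.09 ± 0.29; chromosome 1, 191551251 to 191553131). It lay lower too at Zfp36l2, a protein that promotes mRNA decay, with 58.8 ± 17.7 against 100.1 ± 2.94 (-0.80 ± 0.22).

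None of these regions passed the test. In limma, 0 of 14879 regions had an adjusted p under 0.05 and the smallest adjusted p was 0.987. At an unadjusted p under 0.05 there were 534 regions (256 higher and 278 lower in nicotine), where chance alone gives 744. That count was 352 without saccharin library 3 and 284 with the replicate number as a block. The other named regions on the higher side were Ano2, a calcium-activated chloride channel (log2 difference 1.09), Pcsk1n, which encodes proSAAS (0.96), Csda, a cold shock domain protein (0.89), Ilvbl (0.86), Izumo1, a sperm protein (0.84), Anxa5, an annexin (0.78), and Cnih, a cargo receptor of the endoplasmic reticulum (0.56). On the lower side they were AU015836 (-2.82), Chd9, a chromatin remodeller (-2.59), Adam12, a metalloprotease (-2.56), Zic1, a zinc finger factor of brain development (-1.78), Polq, a DNA polymerase (-1.59), Parm1 (-1.13), Klrg2 (-0.77) and Atxn1l (-0.71). At AU015836, Chd9 and Adam12 the nicotine means were 0.364, 1.07 and 1.80, so these values rest on few adjusted reads and on the pseudocount. The groups did not overlap at 8.95% of regions, and chance gives 10%. The median region had a 95% interval of ± 0.54 on the log2 scale, or 1.45-fold, again unadjusted. Leaving out nicotine library 1, which had the lowest share in the 15 strongest regions (19.1%), turned the count of 0 into 17 (16 higher and 1 lower), among them Ano2, Csda, Izumo1, Bad and Zfp36l2, and into 53 (29 higher and 24 lower) with that share also as a covariate. In these 5 samples the share lay higher in both nicotine samples (41.9% and 49.7%) than in the 3 saccharin samples (28.8% to 39.9%), so the covariate is confounded with treatment, and 2 residual degrees of freedom were left. At an unadjusted p under 0.05 it turned the 534 regions into 1690 (892 higher and 798 lower), and into 1461 with the covariate, both above the 744 of chance.

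At the 5 fixed genes, Ash2l held 130.5 ± 18.9 with nicotine and 107 ± 11.7 with saccharin (SD, n = 3 each), a log2 difference of 0.28 ± 0.18 (SE). Mef2c held 100.1 ± 50.7 and 69.8 ± 10.7 (0.39 ± 0.28), and its difference took the opposite sign with the replicate number as a block (-0.039). The Mef2c difference was 0.81 without nicotine library 1 and 0.023 without nicotine library 4. Chrna4 differed by 0.29 ± 0.28, Chrnb2 by 0.012 ± 0.32 and Chrna7 by 0.09 ± 0.26, and the last of these and Chrnb2 changed sign when single libraries were left out. None of the 5 passed the test.

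3 of the 21 gene lists passed in camera after pre- and postnatal exposure. The mitochondrial respiratory chain genes lay higher in nicotine: 34 of 44 were above 0, with a median of 0.16 on the log2 scale (camera adjusted p = 0.0139, adjusted p = 0.800 with an estimated correlation). Examples were Uqcrc2, of complex III, with 103 ± 19.4 against 75.6 ± 2.57 (SD, n = 3), and Cox6a1, of cytochrome c oxidase, with 159 ± 18.3 against 122 ± 10.2. The call was lost without nicotine library 3 (median 0.12, adjusted p = 0.0843), without nicotine library 4 (0.11, adjusted p = 0.332), without saccharin library 1 (0.11, adjusted p = 0.0715), among the stronger regions alone (0.16, adjusted p = 0.111) and with the replicate number as a block (0.12, adjusted p = 0.186). The median was larger without nicotine library 1 (0.25, adjusted p = 0.00118) and without saccharin library 2 (0.21, adjusted p = 0.00629). The lists were fixed in advance, but no member passed over all regions or when adjusted over the list alone, in this or the other lists. Camera with an estimated correlation is a weak check of the mitochondrial call. In simulated data of this design it called that list, shifted by 0.3 on the log2 scale, in 2 of 5 draws. The other lists were not shifted there, so the simulation does not judge this check for them.

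The developmental homeobox regulators lay lower: 14 of 21 were under 0, with a median of -0.25 (camera adjusted p = 0.0287, adjusted p = 0.811 with an estimated correlation). Among them Hoxa10, a gene of body axis patterning, had 3.58 ± 0.652 against 13.6 ± 8.94 (SD, n = 3) and En2, a gene of midbrain and hindbrain patterning, 70.2 ± 15.6 against 91.6 ± 8.10. With abundance-trended offsets the median was -0.06 (adjusted p = 0.786) and under quantile normalization -0.09 (adjusted p = 0.920). The call was also lost without nicotine library 1 (median -0.20, adjusted p = 0.212), nicotine library 4 (-0.07, adjusted p = 0.644) or saccharin library 1 (-0.06, adjusted p = 0.690), and with the replicate number as a block (-0.34, adjusted p = 0.121). The median was further from 0 without nicotine library 3 (-0.38, adjusted p = 0.00285) and without saccharin library 2 (-0.44, adjusted p = 0.000790). Signal at this list was low: its median saccharin value was 13.6, against 53.7 over all regions.

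The markers of neighbouring regions lay lower as well: 11 of 13 were under 0, with a median of -0.24 (camera adjusted p = 0.0287, adjusted p = 0.711 with an estimated correlation). Tcf7l2 and Lef1, Wnt pathway factors also known from thalamus, had 33.8 ± 7.10 against 50.4 ± 5.48 and 49.0 ± 11.9 against 64.7 ± 3.91 (SD, n = 3). Ppp1r1b, which encodes DARPP-32 of striatal neurons, lay at -0.12 ± 0.25 (SE). The call was lost with abundance-trended offsets (median -0.26, adjusted p = 0.244), under quantile normalization (-0.27, adjusted p = 0.324) and with the block (-0.10, adjusted p = 0.186). It was lost too on leaving out nicotine library 1 (-0.16, adjusted p = 0.0982), 3 (-0.31, adjusted p = 0.0639) or 4 (-0.16, adjusted p = 0.332) or saccharin library 1 (-0.35, adjusted p = 0.0715) or 2 (-0.23, adjusted p = 0.0635). In fry, which asks whether a list moves 1 way without comparing it with other genes, 0 of 21 lists passed (smallest adjusted p = 0.507).

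**Figure D3:**
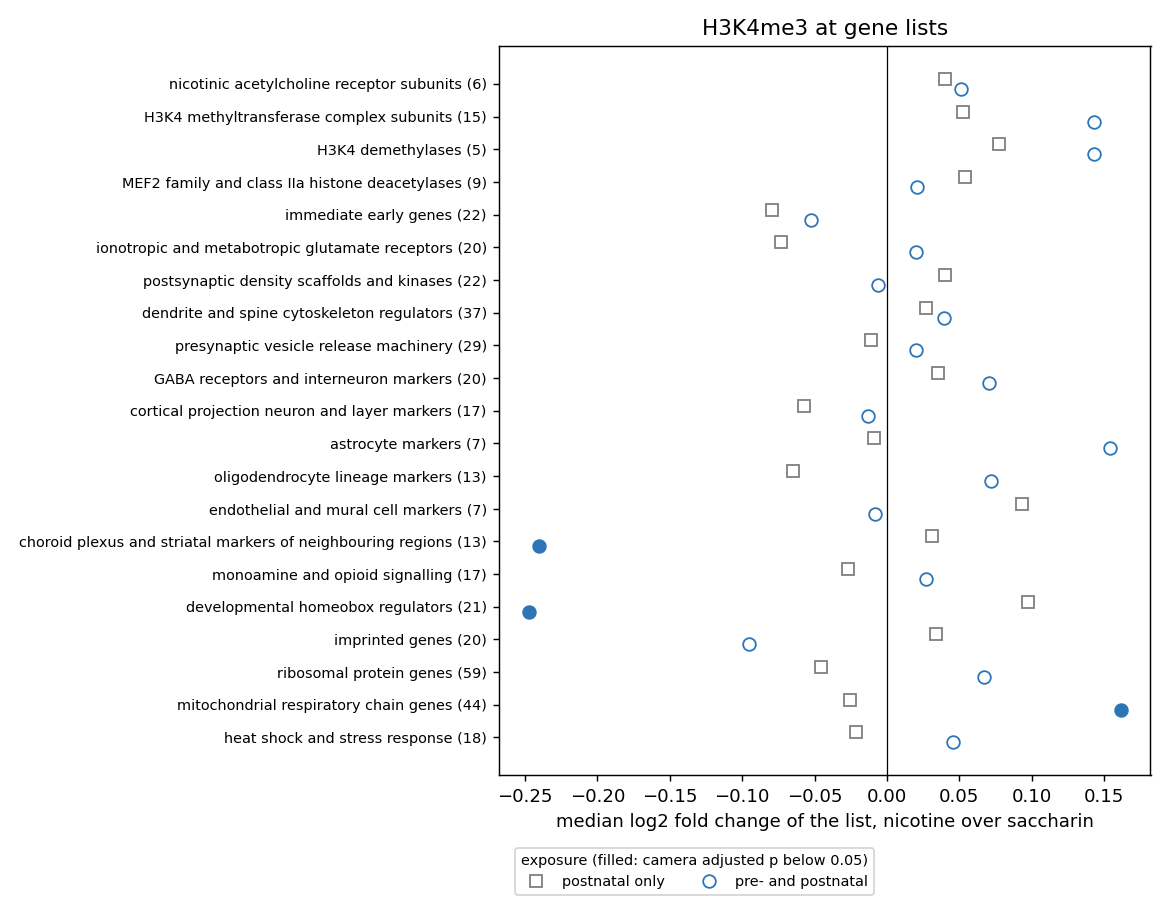
Median log2 fold change of nicotine over saccharin for the 21 tested gene lists, with the number of measured genes in brackets, squares for postnatal and circles for pre- and postnatal exposure. Filled symbols mark the 3 lists with a camera adjusted p under 0.05 (medians 0.16, -0.24 and -0.25). None of these calls held with an estimated correlation. It called a simulated shift of 0.3 of the mitochondrial list in only 2 of 5 draws of this design, and the other lists were not shifted.

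The other lists did not pass after pre- and postnatal exposure. 34 of 59 ribosomal protein genes lay higher (median 0.07, adjusted p = 0.208; Rpl35 0.42, Rps3a 0.39). 9 of 15 H3K4 methyltransferase subunits lay higher (median 0.14), although the members with the lowest p lay lower (Hcfc1 -0.44, Men1 -0.39). 4 of 5 H3K4 demethylases lay higher (median 0.14, with Kdm2b 0.28 and Kdm5a 0.21). Their median was 0.016 without saccharin library 1 and 0.245 without nicotine library 1. The median was 0.02 for 20 glutamate receptor genes, where the AMPA receptor subunit Gria3 lay at 0.77 ± 0.32 (SE) and the NMDA receptor subunit Grin1 at 0.37 ± 0.17. It was -0.05 for 22 immediate early genes (Homer1 0.27, Dusp1 -0.28), 0.07 for 20 GABA receptor and interneuron genes (Erbb4 0.27), -0.01 for 17 projection neuron and layer markers (Camk2a 0.42, Neurod2 -0.31) and 0.03 for 17 monoamine and opioid genes (Adrb1 0.22). It was 0.04 for 37 dendrite and spine regulators (Rac1, a small GTPase of spine growth, 0.40 ± 0.15, and Dbn1 0.33), with the opposite sign under both scalings, and 0.02 for 29 presynaptic genes (Rims2 0.57, Syt2 -0.76), with the opposite sign under quantile normalization. For 22 postsynaptic density genes (Homer2 0.37) the median was -0.01 but the mean 0.02 and the test upward, and the median turned positive under both scalings. For 6 nicotinic receptor subunits (Chrna3 -0.67) the median was 0.05, the mean -0.02 and the direction of camera downward, while fry pointed up. Medians near 0 also changed sign with single libraries. That of the GABA receptor and interneuron genes was -0.012 without saccharin library 1 and -0.033 with the replicate number as a block. That of the projection neuron and layer markers was 0.044, 0.064 and 0.019 without nicotine library 1, 3 and 4.

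Among markers of other cell types, the median was 0.15 for 7 astrocyte markers (Fgfr3 0.32, Slc4a4 -0.20) and 0.07 for 13 oligodendrocyte markers (Nkx2-2 0.80 ± 0.60, SE, and Fa2h -0.41). Without nicotine library 1 these medians were 0.0031 and -0.011. For 7 endothelial and mural markers (Sox17 0.36, Vwf 0.23) the median was -0.01 with a mean of 0.05 and an upward test. It was -0.10 for 20 imprinted genes (Nnat 0.99 ± 0.47, Ndn -1.17 ± 0.64), 0.05 for 18 heat shock and stress genes (Tsc22d3 0.51, Dnajb1 0.36), and 0.02 for 9 MEF2 and class IIa histone deacetylase genes (Hdac9 0.32), where it changed sign under both scalings. Hdac9 also differed between the postnatal samples of high and low share in the 15 strongest regions (high over low 1.22, adjusted p = 0.0258). The lists too small to test had Irf8 at -0.92 ± 0.72 among 4 microglia and macrophage genes, and Pcdha2 at -0.14. The sign of Vwf changed without nicotine library 4 or saccharin library 2, and that of Fgfr3 when regions were summed per gene.

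The third comparison asked whether both exposures altered the mark at the same places. At Rhou, the top postnatal region, the log2 difference of the pre- and postnatal comparison less that of the postnatal one was -0.43, and at Mef2c it was 0.90, with an adjusted p of 1.00 for both. Whether gene lists differed between the exposures was not tested. Over 14871 regions, 0 passed the test of the difference (z from both limma fits, smallest adjusted p = 1.00), and 543 had an unadjusted p under 0.05, where chance gives 744. Fold changes did not go together across regions, which are not independent replicates: Pearson's r was -0.03 and Spearman's coefficient -0.02, and 50.2% of regions had 1 sign in both. 21 of the 30 combinations of other splits of the samples, the real one included, gave an r at least as large in size, and the highest of the others was 0.455. The r turned positive among stronger regions alone (0.06) and without pre- and postnatal nicotine library 4 (0.019). 0 regions passed in both exposures, since 0 passed in either. The difference was called at 5 regions without pre- and postnatal nicotine library 1, named here after their values were seen: Zfp36l2, Tpd52l2, Htra1, Bad and an unnamed region on chromosome 8 (86724137 to 86725878).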

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

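Averaging library pairs, pairs as a random effect, library pairs left out, the terms for repeat share (the share of signal in the 15 strongest regions), alone or with a scaling, and the filters and pseudocounts for lists were chosen after the data had been seen. The fit of 8 separate libraries had been fixed before. Not run, as planned for whole counts only, were RLE size factors, DESeq2, limma-voom and a fit of all 14 libraries. Of 2602 log2 differences at 129 named regions under alternatives, 2558 kept direction and side of the threshold, 13 at 7 regions passed it and 31 at 15 regions changed sign. For the changes given here the cause was not tested, except for the tests under other observations of the lists with abundance-trended offsets and of the calls without nicotine 1. The replicate numbers do not appear to pair samples: deviations of like-numbered samples correlated at -0.465, -0.106 and -0.0982.

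Postnatal counts of 0 (limma, 281 at an unadjusted p under 0.05) became 1 (1 higher) with the block, 9 (8 higher, 1 lower) with repeat class as a term, which is also the crossed pairing and leaves 1 residual degree of freedom, 18 (11 higher, 7 lower) with class and quantile normalization, 21 (19 higher, 2 lower) with class and abundance-trended offsets, 7 lower without nicotine libraries 1 and 2 and 31 higher without 3 and 4 (6 regions in both sets), where the lone sample is assumed to vary like the others. Without any single library they stayed 0. The fits with block, with class or with a pair left out took the variance from a trend shared by all regions. Their calls therefore do not rest on a region's own spread. In the fits with class, the nicotine sample had the higher repeat share within both classes (25.2% against 18.7% and 10.04% against 8.47%). These fits therefore do not part the remaining difference in share from treatment. Of the 8 higher calls with class alone, Ank1, Mdga2, Cdk5rap2 and Litaf also differed between the classes (high over low 1.61, 1.52, 1.47 and 1.41). All 8 libraries as separate samples gave 0 (1375 at an unadjusted p under 0.05, smallest adjusted p 0.281), and pairs as a random effect 0 (488). Pre- and postnatal counts of 0 (534) ranged from 0 to 17 (higher 0 to 16, lower 0 to 1) when each library was left out, the 17 without nicotine 1, and became 53 (29 higher, 24 lower; 11 of the 17 among them) with repeat share as well, a fit in which share and treatment are confounded and 2 residual degrees of freedom remain. Lists passing there numbered 3, and 1 under quantile normalization, 1 with abundance-trended offsets, 0 of the 15 lists that could be tested among regions of higher mean (the mitochondrial list was, the homeobox and neighbouring-region lists had too few genes), 0 with the block, 0 with estimated correlation, 0 in fry, and 0 to 3 without each library (0 without nicotine 4 or saccharin 1). They were 3 with repeat share as a covariate, and 4 without nicotine 1 and with repeat share.

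The correlation of fold changes between exposures was 0.0589 among regions of higher mean and -0.0616 to 0.019 without each library. The difference between exposures was called at 0 to 5 regions without each library and at 2 (Cdk5rap2 and Ank1) with repeat share in both fits. Both regions also differed between the postnatal repeat classes (high over low 1.47 and 1.61). Their calls thus cannot be told from the difference in share that remains within the classes. 1 region was shared at an unadjusted p under 0.01.

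Signs changed at single regions. Postnatal, when 1 library or 1 pair was left out, log2 differences ranged for Chrna4 from -0.0054 to 0.1612, Chrna7 from -0.1809 to 0.1941, Kdm5b from -0.0523 to 0.2446, Irf8 from -0.0118 to 1.1568, Sox17 from -0.024 to 0.4839 and Pcdha2 from -0.2555 to 0.064. Kdm5b was -0.005 with abundance-trended offsets, with or without class, and Fgfr3 0.018 summed per gene. Pre- and postnatal, with 1 library left out, Chrnb2 ranged from -0.208 to 0.21, Chrna7 from -0.2177 to 0.2456 and Vwf from -0.1181 to 0.5793. With the block Mef2c was -0.0392, Chrnb2 -0.3933 and Vwf -0.3852. With repeat share Chrnb2 was -0.04, and summed per gene Fgfr3 was -0.1358. Without nicotine 1 and with repeat share Chrna4 was -0.3715, Chrnb2 -0.2016, Chrna7 -0.243, Kdm2b -0.3335, Sox17 -0.298 and Vwf -0.2194. Past the threshold came Zc3h7a (0.722 without nicotine 3-4, 0.5097 with class, 0.479 and 0.4886 with class and quantile normalization or offsets), Grin2d (0.5399 with class and offsets), and without nicotine 1 Ano2, Csda, Izumo1, Bad and Zfp36l2. Unknown raw depth limits every value.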

Other observations

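The tests of the trend with signal strength, of the striatal markers, of the regions gained without 1 library, of the splits for changed regions and of the correlation between exposures were chosen after the results had been seen. The test of background reads and the splits for gene lists were planned before theirs.

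Postnatal samples with a high share of signal in the 15 strongest regions (nicotine 1-2 and saccharin 3-4) differed from the others at 687 further regions, 571 higher and 116 lower. Among the higher ones were Ank1, an ankyrin of the membrane skeleton (1.61 ± 0.11 on the log2 scale, SE), Cdk5rap2, a centrosomal protein (1.47 ± 0.11), Mdga2, an adhesion protein of synapses (1.52 ± 0.11), and Litaf, an endosomal protein (1.41 ± 0.12). Of the higher regions 35.4% carried no gene, against 23.4% of all regions, and their median signal was 36.1, against 138 for the lower ones.

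At an unadjusted p under 0.05, 17 regions were shared between the 281 postnatal and 532 pre- and postnatal ones, 6 higher in both, 4 lower in both and 7 opposite (one-sided Fisher's exact p = 0.0246, which counts either direction and treats regions as independent). The 10 with a shared direction compare with 5.02 from chance. At an unadjusted p under 0.01 there was 1 shared region, lower in both (one-sided Fisher's exact p = 0.134). As a test of a shared effect of nicotine, the fold changes correlated at -0.0306 over all regions. Since 21 of 30 combinations of splits gave at least that size, this neither shows nor excludes a small shared effect.

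The first pattern is the split of postnatal samples on the first principal component (40.3% of variance). Each side of it held 1 nicotine and 1 saccharin sample. The split by repeat share, which has the same sides, gave 697 regions past the threshold, 687 of them outside the regions that define repeat share. A candidate explanation is a differing share of unenriched background reads: without the repeat regions, the postnatal contrast correlated with the slope on repeat share in the separate pre- and postnatal table (r = 0.471 across regions). Only the regions that define repeat share were left out, and weaker ones beside them on chromosome 9 (such as 3008103 to 3008752) stayed in. The correlation thus does not part background reads from such weaker regions. Other differences between batches of libraries, which the labels do not give, stay open.

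The second pattern is the 3 lists that passed after pre- and postnatal exposure. A trend with signal strength as the whole cause is argued against for the mitochondrial genes, whose median was 0.16 before and 0.148 after trended offsets (adjusted p = 0.0202, but adjusted p = 0.800 with an estimated correlation and no offsets), but it may account for the homeobox regulators, whose median went from -0.25 to -0.0624 (adjusted p = 0.786). For the neighbouring-region markers it stays open, since the median kept its size (-0.24 before, -0.261 after) while the call was lost (adjusted p = 0.244), and so does less striatal tissue in the nicotine dissections, since the 7 striatal members had a median of -0.12 and the 6 others -0.42. Of the 10 splits of the 6 samples 1, the real one, gave 3 lists and the highest other 2, too few splits for a share under 0.05. Most of the other splits gave at least 1 list, so camera also called lists where the split was not that of treatment. An effect of the exposure itself on these lists stays open and untested beyond the comparison reported.

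The third pattern is the 17 regions called after pre- and postnatal exposure without nicotine library 1. Background reads could be the source of some: 5 of the 17 were also higher in the postnatal samples of high repeat share, against 3.91% of all regions, although the median of the 17 in that contrast was 0.126. With repeat share as a covariate 11 of the 17 still passed and 6 did not: 4 of the 5, where the log2 difference shrank (Ank1 from 0.87 ± 0.18 to 0.23 ± 0.19, SE), and Bad (1.20 ± 0.23 to 1.26 ± 0.40) and Zfp36l2 (-1.02 ± 0.21 to -1.07 ± 0.37), where the SE grew, but in these 5 samples both nicotine samples had a higher share than all 3 saccharin samples, so this fit cannot part the covariate from treatment and the source stays open for all 17. With all 6 libraries the count was 0 (534 at an unadjusted p under 0.05, limma), which 10 of 10 splits reach because no count is lower, so this says nothing about chance, and the highest other gave 91, with too few splits for a share under 0.05. That split, nicotine 1 with saccharin 2 and 3 against the rest, follows repeat share and points to a structure of the samples, and with repeat share as a covariate the real split gave 0.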
